A study of Homo sapiens with 8 samples.

How the data were processed

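Gene expression was measured on 8 Agilent 1-colour arrays in BE2(M17), a human neuroblastoma cell line. Per the labels' protocols, cells received 400 pmol of a control siRNA (siSCR) or of an siRNA against ZNF281 (siZNF281) with a lipid reagent and were collected 72 h later, and 100 ng of total RNA was labelled with Cy3. Each group held 4 arrays. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

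Per the file headers, each deposited scanner file was made with Agilent Feature Extraction 10.7.3.1 (the version also stands in the submitters' processing notes) and gives a processed intensity per spot, which is background-subtracted and detrended within the array but not normalized between arrays. The same deposited files give the raw mean intensity and the local background intensity. The authors' deposited value table holds log2 values. Of its probes, 77.8% equalled the log2 processed signal minus the array's 75th percentile once a constant per probe was removed (SD over the 8 arrays under 0.01). That constant, the baseline of the centring, stays unknown, whereas differences between arrays and their direction can be read. Its column medians were -0.297, -0.192, 0.206 and 0.24 for siSCR 1 to 4 and -0.362, -0.137, 0.218 and -0.154 for siZNF281 1 to 4. No per-sample column was left unused.

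Each array held 60901 non-control spots. Between 44.5% and 52.2% of them were well above background, and none was saturated. The 75th percentile of the processed signal was 524, 396, 284 and 248 on the siSCR arrays and 619, 463, 247 and 454 on the siZNF281 arrays. The number of arrays limits the precision. Arrays 1 and 2 of both groups lay on slide 1, and arrays 3 and 4 of both groups on slide 2.

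For the analysis, the main values were log2 of the processed signal minus each array's 75th percentile. Control spots and spots flagged as outliers were left out, and spots of one probe were averaged. Probes well above background on at least 4 of 8 arrays were kept, and the brightest probe (mean over the 8 arrays) stood for its gene. Of 58201 probes, 31104 were named by matching an accession to a RefSeq table of assembly GRCh38.p14, which updated 3367 symbols, 25590 kept the name in the file, and 1507 had no name. Probe positions are on hg19, as in the files. No genome sequence was used, so exon and UTR annotation is not given. In all, 21365 genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no block. Single genes also had an exact two-sided permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286. Python 3.11.15 with pandas 2.3.3 read the files.

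The design, the 33 gene lists and the rule for named genes were fixed before the data were examined. The rule names ZNF281, ZNF148, MYCN, GDNF and NRP2 whatever their values. It further names the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, skipping uncharacterised names. In each list it names up to 4 members past the threshold or, where none passes, the member with the smallest p. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, where at least 5 members were measured. Of 866 list members, 861 were on the array.

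Same-numbered arrays of both groups deviated from their group means together, with correlations across genes of 0.706, 0.577, 0.688 and 0.358, so the replicate numbers were taken as pairs. Arrays with another number on the same slide correlated at 0.38 to 0.682, so most of this pairing follows the slide. Within slides, the difference between the 2 numbers correlated between groups at 0.316 on slide 1 and -0.066 on slide 2, so numbers 3 and 4 show no pairing beyond the slide, and a count over pairs is not support from matched cultures. The alternatives fixed beforehand were quantile normalization, median scaling, normexp (offset 50) with quantile normalization, the authors' value table, no filter on dim probes, a filter for all 8 arrays, the mean of a gene's probes, an intensity trend with a robust prior, array weights, the replicate number as a block, the slide as a block, a limma test against a 1.2-fold change, and leaving out each array. All 20 alternatives and the main fit called no gene. A further 8 models were tried on all arrays. Slide as a block with quantile normalization was first run beside the main fit, and the other 7 were chosen with the data in view, after the main fit and those with the slide or the replicate number as a block were seen to call none. They combine the slide as a block, or the array's 75th percentile as a covariate, with the filter, the normalization or the variance model. Wherever an intensity trend was used, a robust prior came with it. All 8 are reported. First versions of the 2 with quantile normalization, which normalized only the chosen genes and not all probes, called 8 and 29 genes where those reported call 1 and 26. Fits within each slide, and without each array under one of these models, were added too.

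The fits were tested on simulated data for this comparison, with the measured slide effects and residual spread of 21331 genes and 100 genes changed per fold size in each of 5 simulations. The main limma fit recovered 0.2% of genes changed by 1.5-fold and 26.0% of those changed by 2-fold. The fit with slide as a block, an intensity trend and a robust prior recovered 43.8% and 86.6%, with 9.0 false calls per simulation against 0.4 in the main fit. Residuals were drawn independently for each gene, whereas genes on the real arrays vary together. These rates may therefore not carry over to the real calls.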

Results

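The study asked which genes change when ZNF281, a zinc finger transcription factor, is depleted in neuroblastoma cells, in the context of neuronal differentiation. RNA from BE2(M17) cells was profiled 72 h after transfection with a control siRNA (siSCR, 4 arrays) or an siRNA against ZNF281 (siZNF281, 4 arrays). Expression is given as log2 signal relative to each array's 75th percentile, and fold changes are siZNF281 minus siSCR.

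ZNF281 itself was lower on each siZNF281 array than on any siSCR array. Its probe (chromosome 1, 200376333 to 200376392, hg19) read 2.90 ± 0.18 in siSCR and 1.80 ± 0.26 in siZNF281 cells (SD, n = 4 each). The log2 fold change was -1.10 (SE 0.161), a level of 0.466 of the control. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 arrays can give. In limma the adjusted p was 0.427 over all genes and 0.00048 adjusted over the list alone, the list being the 5 genes named beforehand. The log2 fold change was -1.04 within slide 1 and -1.17 within slide 2. With slide as a block the adjusted p over all genes was 0.064.

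GDNF, a neurotrophic ligand of the RET receptor complex, read 1.21 ± 0.26 in siSCR and 1.81 ± 0.32 in siZNF281 cells (SD, n = 4 each), a log2 fold change of 0.60 (SE 0.197). It was higher in 4 of 4 same-numbered pairs. Its limma adjusted p over the list alone was 0.037. That list holds ZNF281, the target of the siRNA, whose small p eases the adjustment for the other genes. The exact permutation p of GDNF was 0.0571, and 0.1427 when adjusted over the 5 genes. Log2 fold changes of the other GDNF probes were 0.21, 0.13 and 0.42. NRP2, a semaphorin receptor, had a log2 fold change of 0.73 (SE 0.359) and was likewise higher in 4 of 4 pairs, with a limma adjusted p over the list alone of 0.124, which became 0.00245 with the replicate number and 0.00358 with slide as a block. By exact permutation the p for NRP2 was 0.1714. Its other probes gave 0.68 and 0.69, each near the floor and well above background on 6 of the 8 arrays. The main NRP2 probe was dim too, with a mean of -2.19 in siSCR cells, though well above background on all 8 arrays. GDNF and NRP2 were named from knowledge of the study, which may have chosen them on these arrays, so their direction is not independent evidence. MYCN, the oncogenic transcription factor of many neuroblastomas, gave -0.07 (SE 0.150). ZNF148, the paralogue of ZNF281, gave -0.14 (SE 0.188) on its brighter probe and 0.38 on the other, so its probes disagreed in sign.

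**Figure D1:**
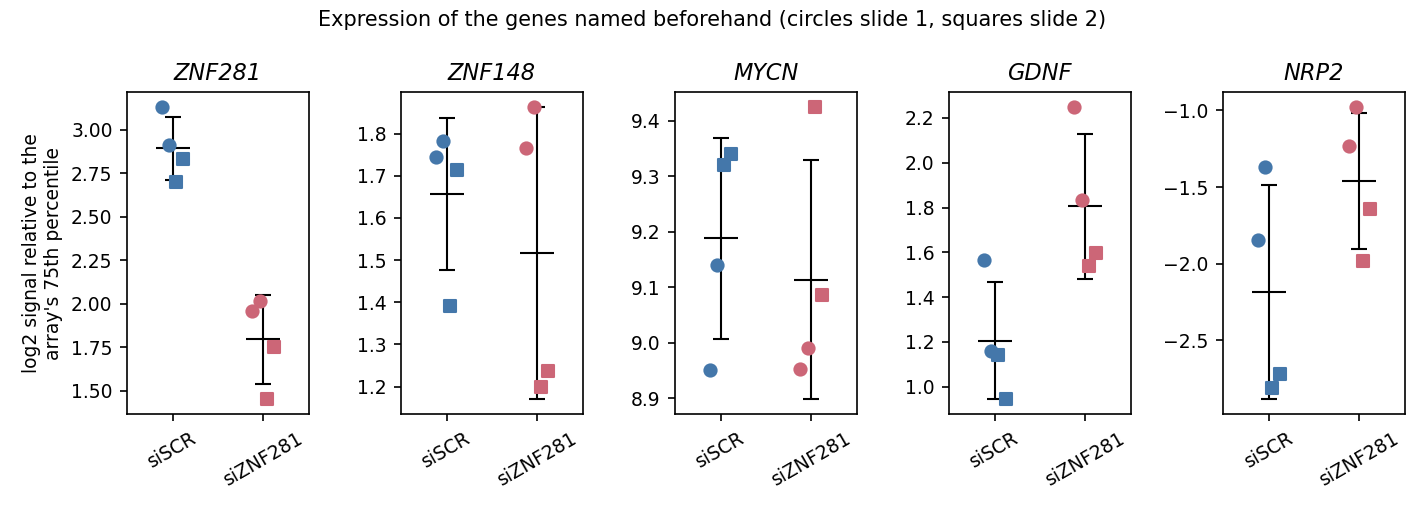
Log2 signal relative to the array's 75th percentile (vertical axes) of the 5 genes named beforehand on each siSCR and siZNF281 array, with circles for slide 1, squares for slide 2, and bars for mean ± SD (n = 4). ZNF281 values do not overlap between groups, with means of 2.90 and 1.80, while those of the other genes do.

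Over all genes, 0 of 21365 passed the threshold in the main limma fit, and 778 had an unadjusted p under 0.05, where chance gives 1068. All 20 alternative settings fixed beforehand also called 0 genes. Slide was the main difference between arrays: the first principal component held 60.05% of the variance and separated the slides, and 8339 genes (39.0%) differed between slides. The median residual SD was 0.272 without the slide in the model and 0.179 with it. With slide as a block, planned beforehand, 2235 genes had an unadjusted p under 0.05 and 0 passed. Log2 fold changes within slide 1 and within slide 2 correlated at 0.248 across genes, which are not independent replicates.

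**Figure D2:**
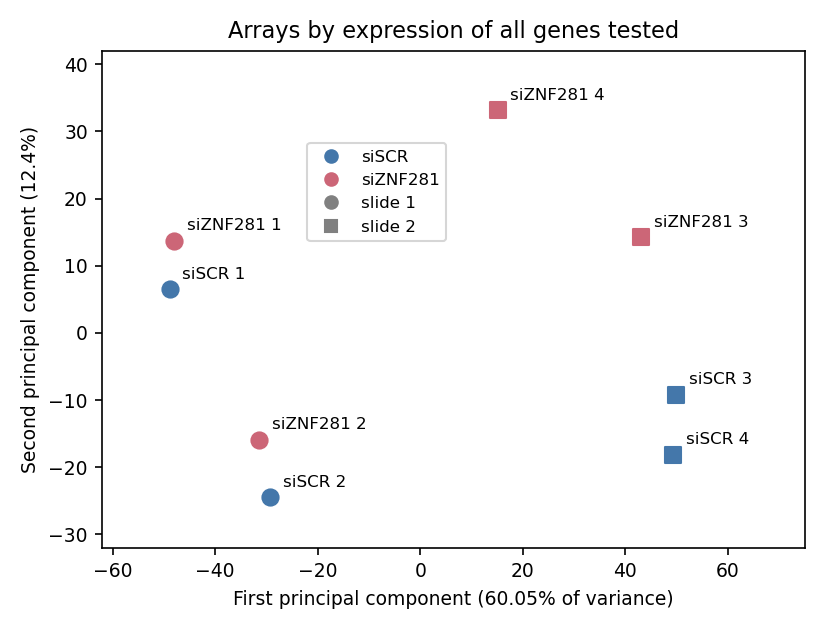
The 8 arrays on the first (horizontal, 60.05% of variance) and second (vertical, 12.4%) principal components of log2 expression, coloured by group, with circles for slide 1 and squares for slide 2. Slide 1 arrays lie between -48.84 and -29.27 on the first component and slide 2 arrays between 15.12 and 49.96.

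A further 8 models were run, 7 of them chosen once the main fit and those with a block were seen to call no gene, and called between 1 and 37 genes. One of them, with slide as a block, an intensity trend and a robust prior, called 28 genes, 7 higher and 21 lower in siZNF281 cells. These genes were therefore chosen after their values were seen. PIGP, which acts in the synthesis of GPI anchors, was called by 8 of the 8 models, with a log2 fold change of -1.02 (SE 0.087 in this model, adjusted p 0.0004165). ZNF281 and RECK, a membrane-anchored inhibitor of matrix metalloproteinases, were called by 7. RECK gave -0.80, CNN1 (the actin-binding protein calponin) -0.79, HACE1 (an E3 ubiquitin ligase) -0.81 and PRSS8 (the serine protease prostasin) -1.09. Among the genes that were higher, LONRF1 gave 0.73, MYH9 (a non-muscle myosin heavy chain) 0.58, S100A11 0.51, MAPRE2 (a microtubule end-binding protein) 0.50 and LAMC1 (a laminin chain) 0.45. Leaving out single arrays in this model moved the count from 28 to between 2 (without siSCR 4) and 137 (without siZNF281 2). In 6 of these 8 fits no gene passed as higher, and LONRF1, MYH9, S100A11, MAPRE2 and LAMC1 each passed in 1, while 2 to 72 genes passed as lower.

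**Figure D3:**
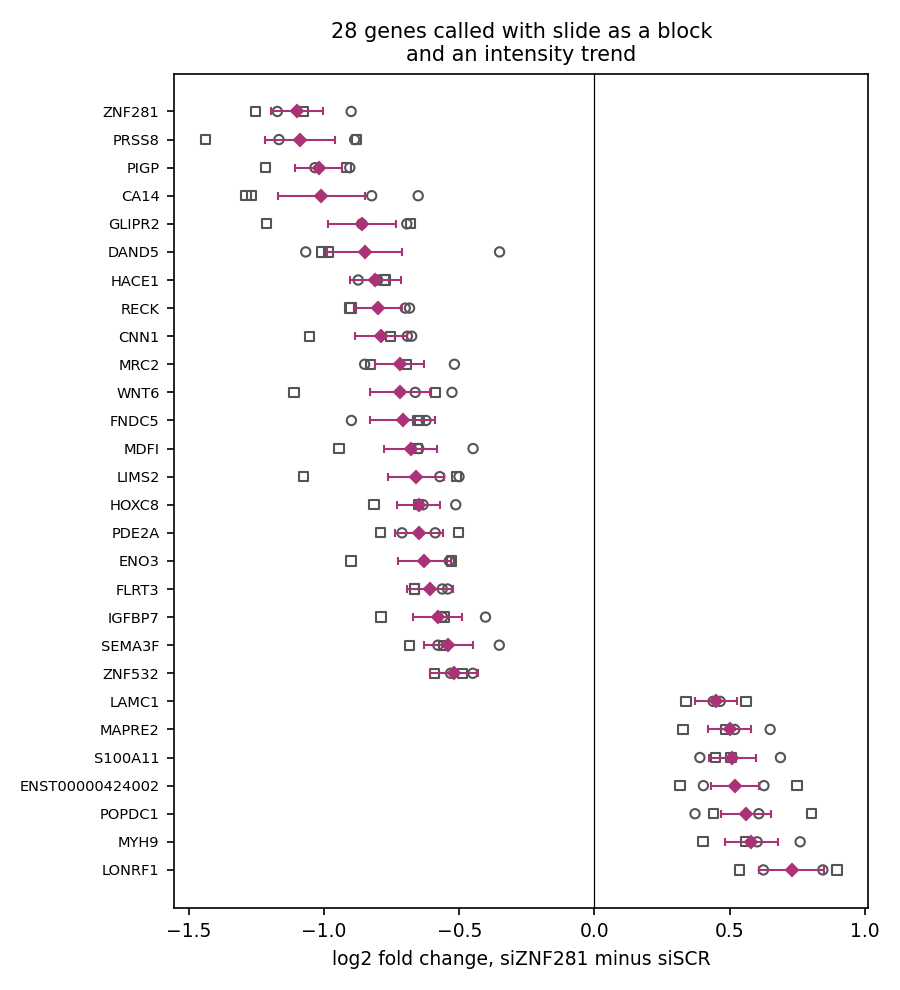
Log2 fold changes (horizontal axis, siZNF281 minus siSCR) of the 28 genes called with slide as a block, an intensity trend and a robust prior. Diamonds and bars mark the estimate ± SE and open symbols the 4 same-numbered pairs (circles slide 1, squares slide 2). The genes were selected by this model; the estimates run from -1.10 for ZNF281 to 0.73 for LONRF1.

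Of 28 measured genes of the neurite and neuronal cytoskeleton, 12 were higher and 16 lower, and 0 passed over all genes or over the list alone. The smallest p belonged to NEFH, a neurofilament subunit, at -0.34. Among 26 synaptic genes, 17 were higher and 0 passed in the main fit, with SYN1 (a synaptic vesicle protein) at 0.49. The list mean was 0.086 and was above 0 in 4 of 4 pairs, with a camera adjusted p of 0.209. With slide as a block BSN at 0.38 and SV2C at -0.34 passed over that list alone (adjusted p 0.0397 each), and with the replicate number neither did. Of 30 noradrenergic genes 16 were higher, and SCG2, a secretogranin, stood at 0.33. Of 18 mesenchymal genes 11 were lower, with LUM, an extracellular matrix proteoglycan, at -0.35. Proneural and Notch genes were lower for 10 of 17 (NOTCH2 -0.22), neural crest specifiers for 10 of 13 (ID1 -0.22) and epithelial-mesenchymal genes for 14 of 19 (MMP2 -0.24). The means of the last 2 were below 0 in 4 of 4 pairs, with camera adjusted p of 0.408 and 0.184. Such runs were not particular to neuronal and identity lists. The glycolysis and endothelial means were also above 0 in 4 of 4 pairs, and the stress response mean below 0 in 4 of 4. NOTCH3, at -0.47, passed over the mesenchymal and the Notch list alone with the replicate number as a block (adjusted p 0.0292 and 0.0276), but not with slide. Stem cell factors were higher for 5 of 10 (BMI1 0.22) and retinoic acid response genes for 4 of 13 (CRABP1 0.26). In the main fit and with either block none of the lists whose members are counted here was called by camera or by fry's test of one direction. BSN, SV2C and NOTCH3 were chosen after their values were seen. Fry's mixed test, which asks whether members change in either direction, called 0 of the 33 lists in the main fit, 12 with slide and 21 with the replicate number as a block. With slide it called the neurite (adjusted p 0.0311), synaptic (0.0159), noradrenergic (0.00653) and mesenchymal (0.00035) lists. It does not compare a list with other genes. With the slide in the model 32.3% of 3300 random lists of equal size had an unadjusted p under 0.05. As many calls came from 3 of 100 random sets of 33 lists. With the replicate number 37% of random lists had such a p, and 0 of 100 sets gave as many calls. This comparison was chosen after these calls were seen. Genes drawn at random need not vary together as members of a fixed list can (estimated correlation 0.509 for mitotic genes in the main fit). The comparison therefore does not show that the lists change more than other genes.

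In the main fit 1 member of the 33 lists passed over its own list, with no adjustment across lists. SEMA3F, a secreted semaphorin that binds NRP2, gave -0.54 (SE 0.116) and was lower in 4 of 4 pairs. It was 1 of 36 measured semaphorin, netrin and slit genes to pass adjusted over the list alone, at an adjusted p of 0.049, and 0 passed over all genes in that fit. It is one of the 28 genes above (adjusted p 0.048 over all genes) and was called by 3 of the 8 models. With the replicate number or slide as a block NRP2 passed over this list as well (adjusted p 0.0265 and 0.0318). In that list 20 genes were higher. Of 15 ephrins and Eph receptors 11 were higher, and the smallest p was that of EPHB3 at -0.41. In the GDNF and neurotrophin list 12 of 25 were higher, and GDNF had the smallest p, and passed over the list alone with the replicate number (adjusted p 0.017) or slide (0.0406) as a block; SPRY4 at 0.54 passed with slide and not with the replicate number. Of 25 voltage-gated channel genes 18 were lower, with the sodium channel SCN2A at -0.42, and with slide as a block the calcium channel CACNA1H at -0.53 passed over the list alone, which it did not with the replicate number. TGF-beta and BMP targets were higher for 7 of 15, and 4 of the 15 passed over the list alone with slide as a block (BMP4 0.92, TGFBI 0.39, SMAD7 0.38 and ID3 -0.28) and 0 with the replicate number, and Wnt targets for 5 of 11 (TCF7 0.27). Fry's mixed test with slide as a block called the GDNF (adjusted p 0.00616), guidance (0.00653), Eph (0.0311) and TGF-beta and BMP (0.00757) lists. As given above, 32.3% of random lists had an unadjusted p under 0.05 in that test. GDNF and NRP2 were named from knowledge of the study, so their passing over these lists is not independent evidence. Other genes named here for a call with a block were chosen after their values were seen.

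S phase genes were higher for 18 of 31 (MCM10 0.28) and mitotic genes for 20 of 34 (PLK1 0.44, camera adjusted p 0.184, which became 0.0313 with normexp and 0.814 with an estimated correlation besides). Cell cycle inhibitors and D cyclins were higher for 5 of 10 (RBL2 0.31), p53 targets for 16 of 25 (TIGAR -0.58) and double-strand break repair genes for 14 of 30 (XRCC3 -0.46). MYC and MYCN targets were higher for 17 of 35 (NOP2 0.35), NuRD subunits for 7 of 13 (GATAD2A 0.30) and interferon response genes for 12 of 24 (IFITM2 0.34). In the main fit no member of these lists passed, over all genes or over the list alone. With the replicate number as a block 3 p53 targets passed over the list alone, TIGAR, CCNG1 at 0.43 and ZMAT3 at 0.40 (adjusted p 0.0277 each), and with slide 0 did, the last 2 genes chosen after their values were seen. The mixed test with slide as a block called the p53 (adjusted p 0.00757), repair (0.0311) and cell cycle inhibitor (0.0477) lists. In that test 32.3% of random lists had an unadjusted p under 0.05, so these calls are not shown to be particular to the lists.

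Cytosolic ribosomal protein genes were the only list called by camera with the preset correlation in the main fit. All 40 were lower, with a list mean of -0.21 and a camera adjusted p of 1.66e-06, and 0 members passed singly (RPL7 -0.22). The call was lost with an estimated correlation (adjusted p = 0.984) and with fry (one direction, adjusted p = 0.977). The list mean was -0.01 under quantile normalization, with a camera adjusted p of 0.841. Without single arrays it was -0.35 to -0.12. Across pairs it was -0.116, -0.14, 0.029 and -0.616, and it was -0.13 within slide 1 and -0.29 within slide 2. Oxidative phosphorylation genes were lower for 18 of 29 (ATP5F1B 0.19) and housekeeping genes for 11 of 17 (YWHAZ 0.19).

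Among metabolic and stress lists, glycolysis and hypoxia genes were higher for 16 of 23 (PFKFB3 0.31, camera adjusted p 0.183, which became 0.0423 under quantile normalization and 0.787 with an estimated correlation besides). Stress and unfolded protein response genes were lower for 24 of 30 (camera adjusted p 0.405), while the member with the smallest p, SLC3A2, stood at 0.24. Cholesterol genes were higher for 11 of 23 (LSS 0.23) and lysosome and autophagy genes for 13 of 23 (LAMP1 -0.23). Of the markers of other cell types, endothelial genes were higher for 4 of 5 (VWF 0.64), with a camera adjusted p of 0.145. That p became 0.0293 with slide as a block and 0.976 with slide as a block and an estimated correlation. With either block VWF and ENG (0.35, chosen after its value was seen) passed over the list alone. With slide, fry's mixed test gave the endothelial list an adjusted p of 0.00616, a test in which 32.3% of random lists had an unadjusted p under 0.05. Schwann and glial markers were lower for 5 of 6 (S100B -0.31, past the threshold over the list alone with slide as a block and not with the replicate number) and blood cell markers higher for 5 of 8 (PTPRC -0.17).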

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

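The tests of single-array influence and of the 4 pairs for the ribosomal proteins, of array brightness for the slides, and the split count for the main fit were chosen or bounded after their results were seen, as was the model behind the 28 genes.

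Within groups of 4 arrays, 6 of 80 sets of values had one array far from the other 3, where chance flags about 1 in 20. Array siSCR 2 read 5.493 for SCG2 against 5.111 to 5.17 on the other siSCR arrays, 2.361 for PLK1 against 1.744 to 1.799, 3.21 for GATAD2A against 2.955 to 2.993, and 5.164 for YWHAZ against 4.913 to 4.948. Array siSCR 1 read 8.184 for XRCC3 against 7.984 to 8.016. Array siZNF281 3 read 2.031 for PLK1 against 2.442 to 2.488.

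The 28 genes called with slide as a block, an intensity trend and a robust prior were examined as a possible response to the siRNA. Chance is not excluded: 2 of the 34 splits of the arrays that this model can fit called as many, the real one with 28 and the highest other with 407. That other split set siSCR 1, siZNF281 1, 3 and 4 against the rest. On slide 2 it is the real comparison, and on slide 1 it sets number 1 against number 2. It is thus not free of the siRNA, and what drives its 407 genes was not tested. The splits that part all 4 pairs are only 8, too few for a share under 0.05 (real 28, highest other 0). A trend on probe GC content is not the whole cause, since 18 of the 28 stayed past the threshold after its trend was removed. Their median absolute log2 fold change went from 0.67 to 0.685. With the array's position on the slide as a covariate that median was 0.66. Only 3 of the 28 then kept a limma adjusted p under 0.05, as the median SE rose from 0.094 to 0.115. Positions were 1, 3, 1 and 2 for siSCR 1 to 4 and 2, 4, 3 and 4 for siZNF281 1 to 4. Position is thus uneven between the groups, and a straight-line covariate separates it from the siRNA only in part. An effect of ZNF281 loss and an off-target effect of the siRNA both remain open and were not tested.

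The lower ribosomal protein genes may be an intensity trend: their median of -0.222 lay at the 4.86th percentile of 10000 lists of equally bright genes, whose own median was -0.188, and the list mean was -0.01 under quantile normalization. Without siZNF281 4 the mean was -0.168 (SE 0.235, 39 of 40 members lower), against -0.211 (SE 0.203) with it. Without other single arrays it reached -0.35 and -0.12, and without the pair of number 4 it was -0.076, so whether single arrays carry the shift is not decided. An effect of the siRNA cannot be told apart, as the mean was 0.029 in the pair that went the other way and below 0 in the other 3.

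The first principal component separated the arrays by slide and not by siRNA. Array brightness went with it as well. In a linear fit on the log2 75th percentile and the slide together, the component went with the percentile (-36.42 per log2 unit, SE 7.07). It still differed between slides by 52.32 (SE 6.67). Without siZNF281 4, the only slide 2 array as bright as those of slide 1, the slide term was 60.43 (SE 12.7, percentile -28.53, SE 12.7). The slides then did not overlap in log2 75th percentile (8.106 to 8.728 on slide 1, 7.423 to 7.646 on slide 2). That fit thus extends a straight line over a gap. Only siZNF281 4, at 15.12 on the component, lay apart from slide 1 at a like brightness. Whether brightness is the whole cause is therefore not settled. Probe intensity and GC content together gave 5.57% of the variance of the slide difference across genes. Separate cultures and separate hybridisations remain open, since the labels name neither, and no biological explanation was tested. With the 4 arrays of each slide set against each other, the main fit called 7859 genes, whereas the real groups gave 0, a count that all 35 of 35 splits reach by definition.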

How the results depend on the processing

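The count of genes changed was 0 in the main fit and in the 20 alternatives fixed beforehand, the replicate block (0 genes, ZNF281 -1.10) and the slide block among them; the replicate block changed no call over all genes. Over each list alone 1 member passed in the main fit, 10 with the replicate block (9 distinct genes) and 14 with the slide block. NRP2 passed over the 5 genes named beforehand with either block. The count over all genes was above 0 only in added models, all but 1 of them chosen after results were seen. Slide as a block gave 28 genes with an intensity trend, 7 with the filter for all 8 arrays, 37 with both, 1 with quantile normalization and 26 with quantile normalization, that filter and the trend. The 75th percentile as a covariate gave 3 with the trend, 19 with slide and trend, and 23 with the filter as well. Single genes were shared unevenly: 44 were called by any of these 8 models and 1 by all. Without single arrays, over the fits fixed beforehand and those added gave 0 to 137 genes. The cause was not tested.

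ZNF281 kept its direction in all 38 alternatives, at -1.20 to -0.99, with limma adjusted p from 0.00034 to 1. It passed over all genes only in added models, at -1.10 with slide and trend, with slide and the filter, and with all 3, at -1.11 with quantile normalization besides, at -1.17 with slide and percentile, with or without the filter, and at -1.20 with the percentile alone. ZNF281 also passed in 8 of the 8 added fits with slide and trend that each left out 1 array, at -1.16 to -1.03. Without single arrays it was -1.17 to -0.99.

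Camera called 1 list in the main fit, 2 with normexp, array weights, the slide block, slide with trend, and slide with quantile normalization, filter and trend, 3 without the filter on dim probes, with the percentile, and with slide, percentile and filter, and 4 with slide and quantile normalization and with slide and percentile. Ribosomal proteins (lower) were called in 18 of the 20 alternatives fixed beforehand, not with quantile normalization, which called only glycolysis, or with normexp. Glycolysis and mitotic genes (higher) were called in 6 each, endothelial genes (higher) in 5, and cholesterol genes (higher) and channels (lower) in 1; epithelial-mesenchymal genes (lower) were called only in added fits. It called 0 with an estimated correlation in any fit, and fry called 0 for one direction in the main fit and with either block. Its mixed test called 0 in the main fit, 21 with the replicate block and 12 with the slide block. Without single arrays the count was 1 to 6.

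Of the 36 other named genes, 33 kept their sign in all alternatives run. MYCN turned to 0.13 with quantile normalization (with slide, and with filter and trend, too), 0.11 with normexp, and 0.02 to 0.03 with the percentile. ZNF148 turned to 0.12 with the mean of its probes and 0.05 within slide 1, RPL7 to 0.01 with normexp, and the endothelial list mean to -0.03 without the filter on dim probes. That setting shifted the median of all genes to -0.10. Signal over background limits the dim probes, as 44.5% to 52.2% of spots were well above it.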

Other observations

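The tests of gene families and of lists between slides were chosen after the data were seen.

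Between slides 39.0% of all genes differed. CHAC1, a glutathione-degrading enzyme of the stress response, was higher on slide 2 by a log2 difference of 2.75 (limma with group in the model, adjusted p 5.82e-05, n = 8 arrays). TH, the rate-limiting enzyme of catecholamine synthesis, was higher by 2.22, the hypoxia gene NDRG1 by 2.10 and the cystine transporter SLC7A11 by 1.72. IGFBP7, an insulin-like growth factor binding protein, differed by -1.95 and the cholesterol synthesis enzyme HMGCS1 by -1.10. Past the threshold over all genes, 13 of 30 stress and unfolded protein response genes were higher on slide 2 and 1 lower, and 13 of 23 glycolysis and hypoxia genes higher and 1 lower. Of 34 mitotic genes 14 passed as lower and 1 as higher (MKI67 -0.56), and of 30 double-strand break repair genes 15 and 2 (BRCA2 -0.83). Camera with the preset correlation called these 4 lists at adjusted p of 0.0317, 0.00826, 0.00098 and 0.000856, besides S phase and cholesterol genes (lower, at 0.0027 and 0.00826) and ribosomal proteins (higher, at 0.000856). No call held with an estimated correlation, where the adjusted p = 0.762 for repair and 0.924 for the other 6, so a difference of these lists beyond that of other genes is not shown. The list means had the same sign in siSCR and siZNF281 cells, at 0.429 and 0.351 for stress, 0.40 and 0.415 for glycolysis, -0.214 and -0.30 for mitosis and -0.287 and -0.286 for repair; these were not tested within groups.

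Of 24 families of genes grouped by name, core histone genes were lower in siZNF281 cells for 52 of 57 (mean log2 fold change -0.177) and kinesin genes higher for 25 of 32 (mean 0.074). With slide as a block the camera adjusted p was 0.00747 and 0.0339, and both calls were lost with an estimated correlation (adjusted p = 0.907 for each). Genes named ZNF were higher for 256 of 432 (mean 0.038), with a camera adjusted p of 0.0456 in the main fit, 0.0634 with slide as a block, and 0.907 with that block and an estimated correlation. The 3 families kept their direction with each scaling run.

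With slide as a block and an intensity trend, 31 members of 14 of the 33 fixed lists (30 genes, 20 of the 31 higher and 11 lower) passed adjusted over the list alone, with no adjustment across lists. In the synaptic list UNC13A gave 0.59, PCLO 0.54, SYN1 0.49, BSN 0.38 and RAB3A 0.33, and in the GDNF list GDNF 0.60, SPRY4 0.54, SPRY2 0.39, SORT1 0.29 and GFRA3 -0.31. Noradrenergic genes gave SCG3 0.48 and SLC6A2 -0.44, and guidance genes NRP2 0.73, SEMA3F -0.54 and PLXND1 -0.45. The Eph list gave EPHB3 -0.41, and channels CACNA1H -0.53 and CACNA2D1 -0.39. Mitotic genes gave PLK1 0.44, KIF11 0.34 and BUB1B 0.28, TGF-beta and BMP targets BMP4 0.92, TGFBI 0.39, SMAD7 0.38 and ID3 -0.28. The others were PRKDC 0.60, GATAD2A 0.30, VWF 0.64, VEGFA -0.37 and NOTCH3 -0.47, which is in 2 lists. Only SEMA3F passed over all genes, and the model was chosen after results were seen. In this model 2390 of all 21365 genes had an unadjusted p under 0.05, where chance gives 1068. How many members random lists would give was not tested, so these calls are not shown to be particular to the lists.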
